A study of Mus musculus with 36 samples.

How the data were processed

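The study sequenced RNA from a purification by HA-tagged ribosomal protein Rpl22 (RiboTag) of mouse tissue. Per the labels the diaphragm samples are synapse-enriched muscle from mice without Cre (Cre-negative) or with ChAT-Cre (Cre-positive), and the spinal cord samples are all Cre-positive. Each tissue and genotype was taken at E15.5, P0.5, P10 and adult age, with 3 libraries per group, which gives 12 groups and 36 libraries. There is no Cre-negative spinal cord sample. The labels do not say whether the 3 replicates of a group are separate animals, so p-values here measure the spread between these samples.

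The deposited table holds 18845 genes, and its values are in CPM, reads scaled to a library total of 1000000: every column adds up to 1000000 over the genes of the table. Per the submitters' processing notes, Bowtie2 2.2.5, RSEM 1.2.12 and the mm10 assembly were used, without further detail on their order. In each library the step of 1 read was fitted to the small values, starting from the smallest positive one, and dividing by it gave values within 0.1 of a whole number in all 36 libraries. In P0.5 Cre-positive replicate 3 this step is close to a round value, where rounding could look alike, so its depth is an estimate. No genome sequence was used here. Of the gene identifiers, 18719 are in the reference list and 18501 of them are protein-coding. The table has 0 mitochondrial gene symbols and 6 genes at 0 in every library.

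Recovered depth was 68.2 to 107 M reads (M, 1000000) in the 24 diaphragm libraries and 63.7 to 71.8 M in the 12 spinal cord libraries. At these depths 3 reads, the floor used for a gene that a group lacks, are well under 0.1 CPM. A gene at 10 CPM thus rests on many reads, and the spread between libraries sets the precision more than counting does.

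Comparisons, gene lists, tests and most alternatives were fixed before the data were examined. The planned test for a table without counts was written for FPKM or TPM values, and it was applied to the CPM values. It is limma 3.58.1 with trend and robust options on log2(CPM + 1), for genes at 1 CPM or more in at least 3 libraries of the fit, in R 4.3.3. Calls are genes with a Benjamini-Hochberg adjusted p under 0.05. A single fit of the 24 diaphragm libraries gave the Cre-positive versus Cre-negative difference at each age, and the change of that difference between neighbouring ages. Each fit shares 1 variance per gene over all its groups, so a p-value also reflects the spread in groups outside the comparison. The 12 Cre-positive diaphragm and 12 spinal cord libraries shared a fit for the tissue comparisons, and the 12 spinal cord libraries alone gave the changes between ages. Adjusted p-values in the text are from limma unless another tool is named. A log2 difference is the difference of group means of log2(CPM + 1), so it is smaller than the ratio of the mean levels for genes near 0.

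The 27 gene lists, fixed beforehand, have 703 members, 702 of them in the table. They cover motor neuron and cholinergic identity, spinal interneuron, sensory neuron, axonal cytoskeleton and growth, axon guidance, synaptic vesicle and release machinery, neurotransmitter receptors, voltage-gated channels, neuromuscular junction postsynaptic, skeletal muscle contractile, satellite cell and myoblast, Schwann cell, oligodendrocyte lineage, astrocyte, microglia and macrophage, endothelial, fibroblast and connective tissue, adipocyte, erythroid, cytosolic ribosomal proteins, translation factors, proteasome, nuclear-encoded respiratory chain, cholesterol synthesis, cell cycle, immediate early genes, and antigen presentation and interferon response. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and again with the estimated correlation, adjusted over the lists and comparisons of a family. Overlaps used the one-sided Fisher exact test. List shares of a library were compared by exact permutation, whose smallest p for 3 against 3 libraries is 0.1.

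Named genes follow a fixed rule. In each comparison candidates are the 8 largest log2 differences per direction among called genes with a mean of at least 10 CPM in the higher group and no overlap between the 2 groups of 3 libraries. From each list the up to 4 called members with the largest difference also qualify, or the 2 most abundant members where no member is called. Chat, Slc18a3, Slc5a7, Rpl22, Acta1 and Ckm are given whatever their result, and genes shared between ages come from the overlaps. Predicted and unnamed genes were left out. Further genes in the closing section were chosen after the data were seen.

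Alternatives were a pseudocount of 0.1, no expression filter, quantile normalization, DESeq2 size factors (RLE), DESeq2 1.42.0 on the recovered reads, a fit of only the compared groups, replicate number as a block, and leaving out each library in turn. Library totals without a TMM factor are what CPM already uses and were not run again. Added after the data were seen were the edgeR 4.0.16 quasi-likelihood test and fits without the intermediate library, or without an outer library, of each group. Labels were also exchanged between libraries, in all 10 splits of 3 against 3 libraries or in 100 drawn splits for the changes between ages.

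The fit was tested on simulated data with 200 changed genes per comparison. In the P0.5 Cre comparison 5.97% of genes changed 2-fold were recovered, 31.3% of those changed 4-fold and 74.2% of those changed 16-fold (4, 21 and 49 genes). There 32 unchanged genes were called beside them, and in the change from E15.5 to P0.5 11 beside 1, 5 and 30 recovered genes, so false calls exceeded the 0.05 share that the threshold allows. In the spinal cord from E15.5 to P0.5 the shares were 98.5%, 100% and 100%, with 18 unchanged genes called, and 17 were called between diaphragm and spinal cord at P0.5. The simulated spread was estimated without the intermediate libraries, and 3 independent libraries were drawn per group, so the recovered shares may be too low for the deposited libraries. Scaling to CPM after genes were changed also shifts the unchanged genes. With 3 independent libraries and no changed gene, the P0.5 Cre comparison gave 0 false calls. Camera picked up a list of 30 genes raised 2-fold and left 30 unchanged genes uncalled in each comparison tried. The simulated genes were drawn independently of each other, so this does not test the preset correlation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.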

Results

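The data cover RNA from the RiboTag purification of synapse-enriched diaphragm (Cre-negative and Cre-positive) and of Cre-positive spinal cord. Ages were E15.5, P0.5, P10 and adult, with 3 libraries in each of 12 groups. Cre-negative libraries hold RNA recovered without Cre and stand for the background of the purification. In the Cre comparisons rose and fell mean higher or lower than that background, not a change of expression. Between ages of spinal cord they mean a change of level in the purified RNA, whose background there was not measured. Depth was 68.2 to 93.7 M reads in Cre-negative diaphragm, 86 to 107 M in Cre-positive diaphragm and 63.7 to 71.8 M in spinal cord. Between 15.4% and 46.2% of genes had no read in a diaphragm library, most of all in Cre-negative diaphragm at P0.5 (35.2% to 46.2%), against 8.3% to 12.9% in spinal cord. Levels below are mean ± SD in CPM.

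In each group the library best written as a weighted sum of the other 2, with positive weights, was taken as the intermediate library. In 9 of the 12 groups it was replicate 3. Genes at a level between those of the other 2 libraries made up 49.4% to 84% for it (median 75.1%). For the outer libraries the range was 3.4% to 37.3%. The choice itself favors a profile close to the weighted sum. The weights of that sum, which the choice left free, added up to 0.987 to 1.01. The distance from that sum was 2.97 to 8.57 times the counting error, while the outer libraries of a group stood 6.92 to 619 times apart. Simulated libraries without any difference, of which 1 in 3 was mixed from the other 2, gave 1856, 1134, 1144 and 842 false calls in the Cre comparisons at E15.5, P0.5, P10 and adult age. With 3 independent simulated libraries the numbers were 41, 0, 1 and 2. The deposited libraries gave 1522, 3844, 201 and 1659 calls. The counts at E15.5 and P10 thus do not exceed what a mixed library gives without any difference. Genes with many reads in 1 outer library and 0 in the other stood in the intermediate library at close to its fitted weight. Median ratios in Cre-negative diaphragm were 0.211 and 0.793 against weights of 0.207 and 0.789 at P0.5. At P10 they were 0.612 and 0.41 against 0.611 and 0.391. The furthest in diaphragm was 0.586 against 0.685, in adult Cre-positive. The weights were fitted to reads that include these genes, so part of this closeness was set in advance. With that limit the values argue against 3 independent libraries in diaphragm, while spinal cord had too few such genes. How the intermediate libraries arose is open. Each count between Cre-positive and Cre-negative diaphragm thus stands beside the count without them. Leaving the intermediate libraries out changed the size of the named differences little: 88 of 88 named calls kept their direction, and the median ratio of the log2 differences without and with them was 1.02, 0.99, 1.01 and 1 from E15.5 to adult. A library close to a weighted sum of the other 2 can move a group mean little. Many of these genes were also chosen for groups that do not overlap. The small changes were thus largely set in advance and add no support to the differences. Standard errors of these genes grew by a median factor of 1.49, 1.52, 1.76 and 1.63, where 2 in place of 3 libraries alone give 1.22. With an outer library left out of each group instead, also 2 per group, the factors were 0.76, 0.64, 0.66 and 0.64 (the lower-numbered) or 1.13, 1.16, 1.19 and 1.21 (the higher-numbered), and 4844, 6881, 2121 and 4937 or 762, 3131, 16 and 758 genes were called. The intermediate library lies between the other 2 by choice, so leaving it out leaves the pair furthest apart. The larger standard errors and the lost calls could follow from that choice. A mixed library could give the same loss. In the simulated data with a mixed library and no difference, 35, 1, 0 and 0 false calls were left without it. The lost calls thus do not tell the choice and a mixed library apart. These factors can therefore not be read against 1.22 alone.

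**Figure D1:**
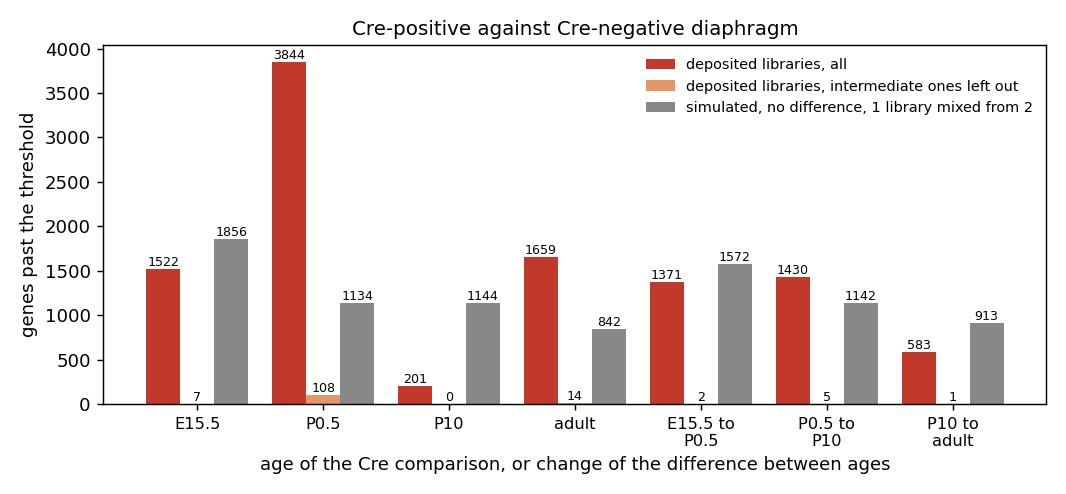
Genes past the adjusted p threshold of 0.05 in the Cre-positive versus Cre-negative diaphragm comparisons, with all libraries, without the intermediate library of each group, and in simulated data without a difference in which 1 library was mixed from 2. Each group has 3 libraries.

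The diaphragm and spinal cord libraries differed in muscle and motor neuron transcripts. The skeletal muscle contractile list made up 24 ± 0.681% of all CPM in Cre-negative and 22.5 ± 0.457% in Cre-positive diaphragm at P0.5 (n = 3), against 0.5% in spinal cord. At E15.5 it made up 10.5 ± 1.08% and 9.52 ± 1.04%, less than the erythroid list (12.2 ± 0.323% and 16.4 ± 4.61%). The motor neuron and cholinergic list made up 0.00303% to 0.016% of diaphragm libraries by group and 0.404% to 0.506% of spinal cord libraries. Chat, the acetylcholine-synthesizing enzyme whose promoter drives Cre here, had 0 reads in all 12 Cre-negative libraries. In Cre-positive diaphragm it had 14, 0 and 7 reads at E15.5, 0 in every library at P0.5, 0, 4 and 0 at P10, and 0, 0 and 2 in the adult. Slc18a3, the vesicular acetylcholine transporter, had 2, 123 and 30 reads in Cre-positive diaphragm at E15.5 and 0 in each Cre-negative library of that age. Slc5a7, the choline transporter, had 33, 17 and 32 reads in Cre-positive and 0 in each Cre-negative library at E15.5, but 1, 0 and 0 in Cre-positive and 131, 0 and 47 in Cre-negative diaphragm at P0.5. In spinal cord Chat averaged 15.9 ± 0.261, 11.5 ± 1.2, 64.9 ± 8.5 and 64.6 ± 3.09 CPM from E15.5 to adult (n = 3).

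**Figure D2:**
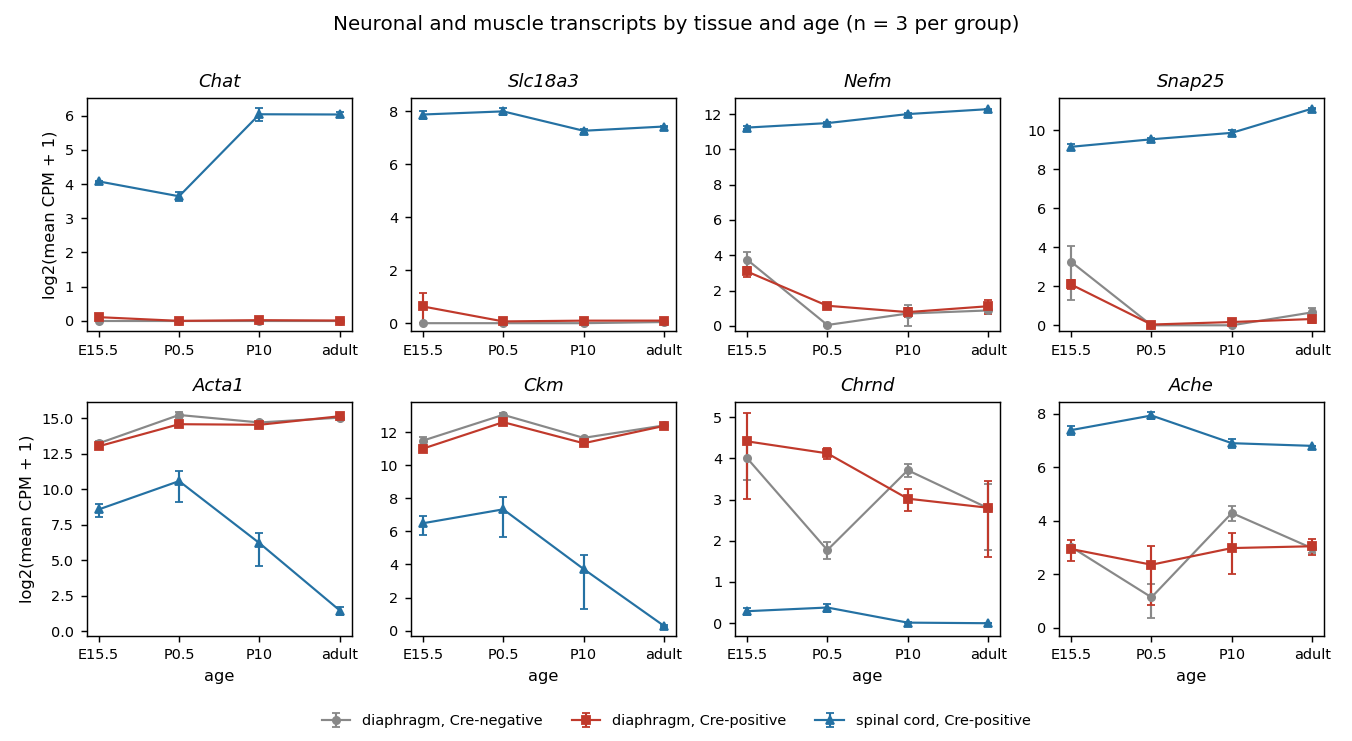
Neuronal (Chat, Slc18a3, Nefm, Snap25), muscle (Acta1, Ckm) and synaptic (Chrnd, Ache) transcripts in the 3 sample types over age. Points are mean and SD of 3 libraries in CPM on a log2 scale after adding 1.

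At E15.5 the largest rises in Cre-positive diaphragm included cartilage genes. Comp, a matrix protein of cartilage and tendon, was at 158 ± 126 against 0.221 ± 0.223 CPM (n = 3; log2 difference 6.30, adjusted p = 4.1e-06), and Mia, a cartilage secreted protein, at 1201 ± 927 against 20.2 ± 6.6 (5.21, 1.9e-04). Col2a1, the main cartilage collagen, rose from 29.8 ± 37.6 (8.52 without replicate 1) to 640 ± 476 (5.13, 0.0014) and Cnmd from 1.83 ± 1.86 to 57 ± 37.7 (4.21, 1.6e-05). Pvalb, the calcium buffer of fast muscle and of some neurons, was at 83.2 ± 8.02 against 8.16 ± 0.532 (3.20, 1.2e-07), and Uqcr11, a subunit of respiratory complex III, at 8039 ± 452 against 3382 ± 378 (1.25, 4.1e-06). Without the intermediate libraries, Pvalb (adjusted p = 0.0027), Uqcr11 (0.016) and Comp (0.049) kept their calls. Mia (0.25), Col2a1 (0.4) and Cnmd (0.2) did not. A cartilage list chosen after the data were seen made up 0.382 ± 0.284% of Cre-positive and 0.0343 ± 0.0238% of Cre-negative libraries (exact permutation p = 0.2, where 0.1 is the smallest possible).

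The interferon-response genes Isg15, Irf7 and Ifitm3 had calls in Cre-positive diaphragm at E15.5. Isg15 was at 47.3 ± 16.3 against 4.42 ± 4.05 CPM (n = 3; 3.61, adjusted p = 0.0023), Irf7 at 5.42 ± 1.78 against 0.732 ± 0.638 (1.94, 0.006) and Ifitm3 at 280 ± 6.62 against 88.5 ± 29.4 (1.70, 5.3e-05). Of 20 antigen presentation and interferon genes 4 rose, 0 fell and 16 were not past the threshold (9 and 0 adjusted over the list alone; median 0.78, adjusted p = 3.5e-04, and adjusted p = 0.77 with an estimated correlation). Of genes for digestive enzymes, Amy2a5 fell from 277 ± 144 to 56.8 ± 49.3 (-3.43, 0.02), Pnliprp1 from 172 ± 90 to 42.2 ± 36.1 (-2.92, 0.022) and Cpa1 from 60.6 ± 19.7 to 15.8 ± 13.8 (-2.72, 0.019; 10.5 without Cre-positive replicate 1). Col3a1, a fibrillar collagen of connective tissue, fell from 1086 ± 15.9 to 375 ± 86.3 (-1.56, 0.0015), and Col1a1 from 877 ± 58.4 to 395 ± 46.5 (-1.15, 0.0046). Rps7 was lower at 816 ± 18.9 against 1520 ± 172 (-0.89, 0.015) and Rpl4 at 1231 ± 123 against 2025 ± 90.6 (-0.72, 4.4e-04). The calls of Isg15 (adjusted p = 0.31 without the intermediate libraries), Irf7 (0.49), Ifitm3 (0.22), Amy2a5 (0.43), Pnliprp1 (0.44), Cpa1 (0.44), Col3a1 (0.41), Col1a1 (0.45), Rps7 (0.54) and Rpl4 (0.35) were lost, although their differences stayed close, for instance 4.08 for Isg15, 2.18 for Irf7, -1.50 for Col3a1 and -0.76 for Rpl4. Of 79 cytosolic ribosomal protein genes 5 rose, 21 fell and 53 were not past the threshold, whereas 7 rose and 3 fell with RLE size factors (9 and 31 adjusted over the list alone; median -0.19, adjusted p = 0.0012, and adjusted p = 0.9 with an estimated correlation).

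Rpl22, the gene that carries the RiboTag allele, was lower in Cre-positive diaphragm at E15.5, at 46.5 ± 5.07 against 82.1 ± 8.47 CPM (n = 3; log2 difference -0.81, adjusted p = 0.039, and 0.7 without the intermediate libraries). Among muscle genes, Acta1 was at 8405 ± 848 against 9700 ± 927 (-0.21, 0.15) and Ckm at 2042 ± 202 against 2857 ± 437 (-0.48, 0.005, and 0.45 without the intermediate libraries). Motor neuron transcripts gave no shared direction: of 17 tested genes of the motor neuron and cholinergic list 1 rose, 1 fell and 15 were not past the threshold (1 and 1 adjusted over the list alone), with a median of -0.10, a mean of 0.12 and a test direction of up (adjusted p = 0.94). Of 13853 tested genes 1522 were past the threshold at E15.5, 676 higher and 846 lower, and 7 without the intermediate libraries (1036 at unadjusted p under 0.05). RLE size factors moved the median of all genes from -0.06 to 0.06 and gave 820 higher and 529 lower. The count fell to 828 without Cre-negative replicate 2, 853 without Cre-positive replicate 1 and 693 without Cre-positive replicate 3.

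At P0.5 the largest rises included liver transcripts. Apoc2, an apolipoprotein made by hepatocytes, was at 487 ± 552 CPM in Cre-positive against 0.291 ± 0.056 in Cre-negative diaphragm (n = 3; log2 difference 7.93, adjusted p = 1.5e-09). Apoa1 was at 1309 ± 1493 against 16.1 ± 11 (5.96, 7.4e-05), Ttr at 371 ± 386 against 5.52 ± 6.5 (5.84, 5.7e-05) and Fabp1 at 1819 ± 2090 against 42.5 ± 37.1 (5.99, 7.9e-04). Cartilage transcripts were again higher, with Col2a1 at 143 ± 72.9 against 0.328 ± 0.402 (6.69, 4.7e-05) and Mia at 70.1 ± 27.8 against 0.0682 ± 0.0591 (5.99, 1.9e-05). Lyz2, the lysozyme of macrophages and neutrophils, rose from 1.07 ± 1.43 to 25.8 ± 5.98 (3.89, 2.6e-07). All of these kept their calls without the intermediate libraries except Fabp1 (adjusted p = 0.053). Cre-positive replicate 2 stood apart for the liver genes: without it the Cre-positive means were 169 CPM for Apoc2, 448 for Apoa1, 149 for Ttr and 613 for Fabp1, and the differences 7.02, 5.04, 5.02 and 5.06 were still past the threshold (adjusted p = 2.0e-10, 4.4e-04, 3.4e-04 and 0.0058). The libraries left, replicates 1 and 3, stood only 2.99 times the counting error apart, and replicate 1 was close to replicate 3 alone (weight 0.957). These adjusted p-values may thus rest on Cre-positive libraries that are not independent. Ttr in Cre-negative diaphragm was at 1.82 without replicate 1.

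**Figure D3:**
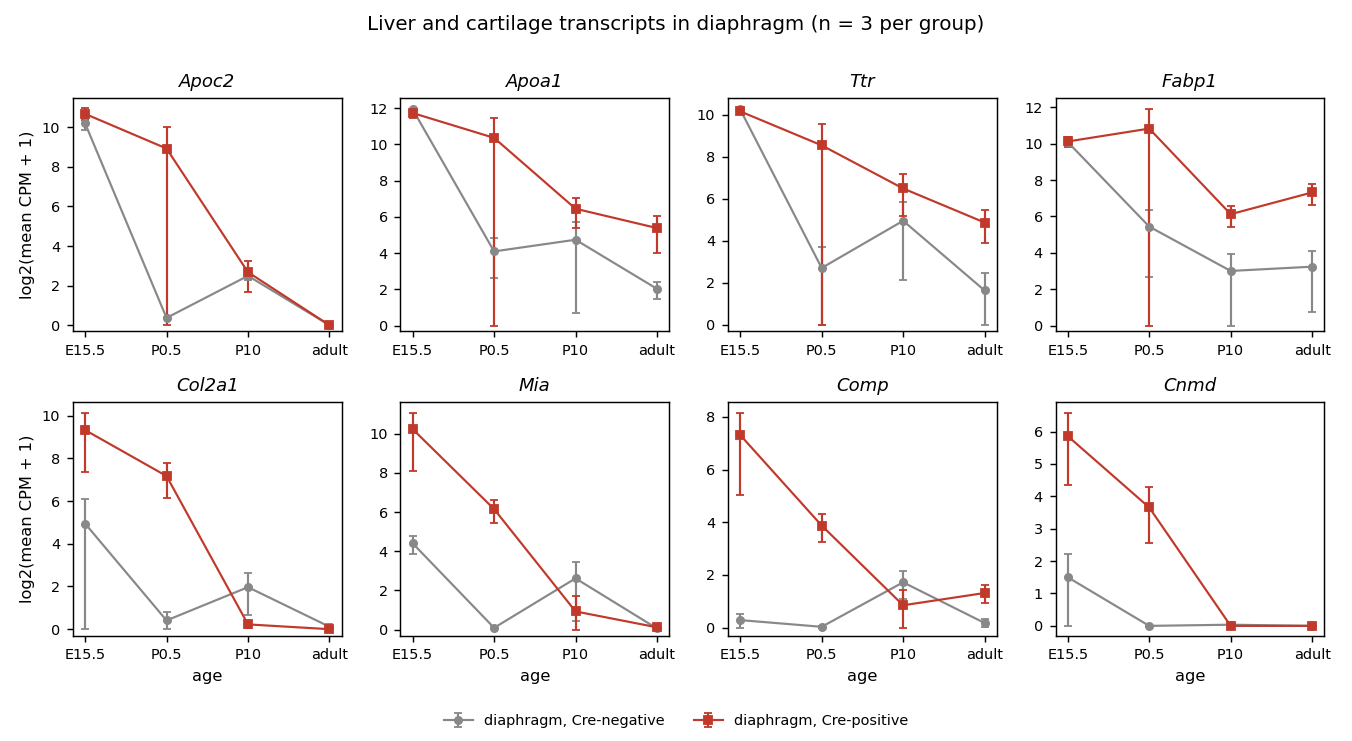
Liver (Apoc2, Apoa1, Ttr, Fabp1) and cartilage (Col2a1, Mia, Comp, Cnmd) transcripts in Cre-negative and Cre-positive diaphragm over age. Points are mean and SD of 3 libraries in CPM on a log2 scale after adding 1.

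Uqcr11, Ndufa3 and Ndufb8, genes of the respiratory chain, were higher at P0.5. Uqcr11 was at 17802 ± 4399 against 6050 ± 786 CPM (n = 3; 1.53, adjusted p = 1.7e-07), Ndufa3 at 5579 ± 881 against 2170 ± 415 (1.37, 9.4e-08) and Ndufb8 at 5106 ± 1145 against 2369 ± 221 (1.08, 6.0e-06), and each kept its call without the intermediate libraries. Of 75 nuclear-encoded respiratory chain genes 28 rose, 5 fell and 42 were not past the threshold (30 and 10 adjusted over the list alone; median 0.20, adjusted p = 2.7e-04, and adjusted p = 0.9 with an estimated correlation). Among contractile genes Myh8, the perinatal myosin heavy chain, fell from 1879 ± 929 to 585 ± 265 (-1.66, 3.0e-04), Ttn from 35 ± 15.2 to 11.3 ± 10.5 (-1.79, 0.0052) and Neb from 115 ± 33.2 to 38.4 ± 22.6 (-1.66, 0.0016). Acta1 fell from 38805 ± 5507 to 24733 ± 1023 (-0.64, 5.5e-05, and 0.025 without the intermediate libraries) and Ckm from 8449 ± 728 to 6208 ± 344 (-0.44, 0.0032). The calls of Myh8 (adjusted p = 0.11 without the intermediate libraries), Ttn (0.23), Neb (0.16) and Ckm (0.2) were lost. Without Cre-positive replicate 2 the mean of Ttn there was 5.28 and of Neb 25.4. Of 38 skeletal muscle contractile genes 3 rose, 21 fell and 14 were not past the threshold, whereas 9 rose and 6 fell with RLE size factors (5 and 22 adjusted over the list alone; median -0.44, adjusted p = 7.1e-04, and adjusted p = 0.9 with an estimated correlation).

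At P0.5 Hba-a1 rose from 2419 ± 74.4 to 3861 ± 1229 CPM (n = 3; 0.63, adjusted p = 0.038), Hbb-bt from 484 ± 148 to 930 ± 454 (0.89, 0.018) and Alas2, the erythroid heme enzyme, from 0.947 ± 0.779 to 6.38 ± 3.77 (1.91, 8.8e-04). Of 11 erythroid genes 4 rose, 0 fell and 7 were not past the threshold (4 and 0 adjusted over the list alone; median 0.57, adjusted p = 0.048, and adjusted p = 0.9 with an estimated correlation). Mlkl, the effector of necroptosis, fell from 23.5 ± 13.6 to 0.356 ± 0.208 (-4.05, 1.4e-06, and 0.014 without the intermediate libraries). Myf5, a satellite cell factor, fell from 151 ± 104 to 13.4 ± 15.7 (-3.74, 1.6e-04), and the small GTPase gene Gem from 34.5 ± 1.24 to 2.25 ± 1.49 (-3.58, 1.1e-04). At the postsynaptic membrane, Chrnd, an acetylcholine receptor subunit, rose from 2.42 ± 0.469 to 16.4 ± 1.55 (2.35, 0.0021) while Lrp4, the agrin receptor, fell from 71.5 ± 42.1 to 12.3 ± 12.7 (-2.72, 7.8e-04). Calls were lost for Hba-a1 (adjusted p = 0.23 without the intermediate libraries), Hbb-bt (0.12), Alas2 (0.094), Myf5 (0.08), Gem (0.055), Chrnd (0.17) and Lrp4 (0.14). Without Cre-positive replicate 2 the mean of Myf5 there was 4.37, of Lrp4 4.95 and of Alas2 4.21, and without Cre-negative replicate 1 Myf5 was at 92.1 and Lrp4 at 47.6. Of 17 neuromuscular junction postsynaptic genes 2 rose, 4 fell and 11 were not past the threshold (2 and 4 adjusted over the list alone; median -0.19, adjusted p = 0.76), and the median was 0.20 with quantile normalization and 0.23 with RLE.

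Rpl22 fell at P0.5 from 32.7 ± 12.5 to 15.8 ± 2.74 CPM (n = 3; -0.94, adjusted p = 0.008, and 0.34 without the intermediate libraries). Of 17 motor neuron and cholinergic genes 1 rose, 5 fell and 11 were not past the threshold (1 and 5 adjusted over the list alone; median -0.41, adjusted p = 0.48). In total 3844 genes were past the threshold, 1672 higher and 2172 lower, and 108 without the intermediate libraries, 89 higher and 19 lower. A fit of only the P0.5 groups called fewer genes than this fit of all ages. With RLE size factors 2617 were higher and 1291 lower, and the median of all genes moved from -0.01 to 0.21.

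At P10 limma called 0 genes without the intermediate libraries (246 at unadjusted p under 0.05), while the differences of the 16 named calls stayed within 0.95 to 1.05 times their size, for instance Apoc3 at 3.53, Ucp1 at 2.74 and C1ra at 2.35. Apoc3, a liver apolipoprotein, was at 22.8 ± 11.5 CPM in Cre-positive against 1.25 ± 1.28 in Cre-negative diaphragm (n = 3; log2 difference 3.47, adjusted p = 0.022) and Hpx, the plasma heme binder, at 13.6 ± 11.9 against 0.738 ± 0.869 (2.79, 0.02). Without Cre-positive replicate 2 Hpx was at 7.07 there and its call was lost (2.14, adjusted p = 0.13). The complement proteases C1ra (512 ± 203 against 94.7 ± 7.77; 2.35, 0.017) and C1s1 (219 ± 88.3 against 73.8 ± 2.25; 1.48, 0.045) were higher. So was Retnlg, a neutrophil product, at 10.3 ± 1.03 against 1.27 ± 1.33 (2.48, 0.011). Ucp1, the uncoupling protein of brown fat, was at 7.85 ± 0.443 against 0.382 ± 0.36 (2.71, 2.9e-05). Of 7 adipocyte genes 1 rose, 0 fell and 6 were not past the threshold (2 and 0 adjusted over the list alone; median 0.59, adjusted p = 3.8e-05, and adjusted p = 0.011 with an estimated correlation). The share of the adipocyte list went the other way, at 0.315 ± 0.00674% in Cre-positive against 0.339 ± 0.0191% in Cre-negative libraries (exact permutation p = 0.1, the smallest possible), and was also lower in Cre-positive libraries at the other ages.

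Mymk, Myh2 and Mag were among the genes lower at P10. Mymk, the myoblast fusion protein, fell from 26.1 ± 1.62 to 9.69 ± 4.05 CPM (n = 3; -1.41, adjusted p = 0.028) and Myh2, the fast IIa myosin, from 240 ± 20.9 to 96.6 ± 20.1 (-1.32, 0.013). Of 38 skeletal muscle contractile genes 0 rose, 1 fell and 37 were not past the threshold (0 and 6 adjusted over the list alone; median -0.21, adjusted p = 0.049, and adjusted p = 0.9 with an estimated correlation). Mag, a myelin glycoprotein, fell from 3.72 ± 0.734 to 0.581 ± 0.54 (-1.63, 0.013). Of 15 Schwann cell genes 0 rose, 1 fell and 14 were not past the threshold (0 and 5 adjusted over the list alone; median -1.04, adjusted p = 3.5e-04, and adjusted p = 0.1 with an estimated correlation). For 16 fibroblast and connective tissue genes 0 rose, 0 fell and all were short of the threshold (0 and 0 adjusted over the list alone; median -0.46, adjusted p = 0.014, and adjusted p = 0.9 with an estimated correlation). Psmc2 fell from 45.1 ± 9.77 to 17.1 ± 2.17 (-1.34, 0.009) and Psmd6 from 119 ± 13 to 53.9 ± 7.61 (-1.13, 0.0069). Of 31 proteasome genes 0 rose, 3 fell and 28 were not past the threshold, and the median of -0.18 was 0.01 with RLE (0 and 4 adjusted over the list alone; adjusted p = 0.048, and adjusted p = 0.9 with an estimated correlation).

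At P10 the ribosomal protein gene Rpl30 was higher, at 1377 ± 70 against 922 ± 45.5 CPM (n = 3; 0.58, adjusted p = 0.0041). Of 79 cytosolic ribosomal protein genes 1 rose, 0 fell and 78 were not past the threshold (3 and 0 adjusted over the list alone; median 0.16, adjusted p = 7.4e-13, and adjusted p = 0.9 with an estimated correlation). Etfbkmt, a mitochondrial methyltransferase gene, fell from 15 ± 2.66 to 1.5 ± 0.379 (-2.68, 0.0026). Acta1 (24037 ± 302 against 26917 ± 277; -0.16, 0.48), Ckm (2565 ± 89.8 against 3212 ± 162; -0.32, 0.14) and Rpl22 (27.5 ± 2.83 against 31.3 ± 4.11; -0.18, 0.85) were not past the threshold. None of 17 motor neuron and cholinergic genes was past it (adjusted p = 0.58). In total 201 genes were past the threshold in limma, 58 higher and 143 lower (78 and 80 with RLE, 123 and 121 with quantile normalization). A fit of only the P10 groups called more genes, so the lower count than at P0.5 depends on the choice of fit. The median of all genes was -0.13, and 0.00 with either of these scalings. Without the intermediate libraries limma called 0 genes, with 246 at unadjusted p under 0.05, while with all libraries edgeR called 48 and DESeq2 599. The count was 93 without Cre-negative replicate 1, 44 without Cre-negative replicate 3, 124 without Cre-positive replicate 2 and 48 without Cre-positive replicate 3.

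In the adult, the liver genes Fabp1, Alb and Apoa2 were higher in Cre-positive diaphragm, and Abracl and Ube2v2 were lower. Fabp1 was at 159 ± 61.6 against 8.46 ± 7.79 CPM (n = 3; log2 difference 4.76, adjusted p = 0.0094), Alb at 23.3 ± 9.61 against 1.06 ± 1.13 (3.64, 0.0018) and Apoa2 at 56.8 ± 18.2 against 6.24 ± 5.72 (3.57, 0.0023). In Cre-negative diaphragm Fabp1 was at 5.03 without replicate 2 (difference 5.52) and Apoa2 at 3.75 without replicate 3 (4.26). Of other liver genes, Mup20 was at 12.7 ± 1.38 and Serpina3k at 11.2 ± 0.468, both listed at 0 in Cre-negative diaphragm (adjusted p = 2.2e-08 and 2.9e-07, and 0.014 and 0.04 without the intermediate libraries). Abracl fell from 48.8 ± 2.7 to 1.57 ± 1.27 (-4.43, 4.9e-08, and 0.0036 without the intermediate libraries) and Ube2v2, a ubiquitin-conjugating enzyme variant, from 74.7 ± 30.5 to 4.8 ± 1.78 (-3.66, 2.2e-07, and 0.019 without them). Wdr31 was at 35 ± 14.8 against 1287 ± 1041 (-4.67, 2.5e-05; Cre-negative 789 without replicate 3). Psmb9, an immunoproteasome subunit, was higher at 7.05 ± 2.13 against 0.173 ± 0.3 (2.78, 0.0016), whereas Psmc2 fell from 51.6 ± 12.4 to 14.4 ± 1.53 (-1.75, 1.0e-04) and Psmc6 from 137 ± 19 to 41.1 ± 7.66 (-1.73, 4.9e-04). Rps7 fell from 814 ± 308 to 333 ± 25.2 (-1.21, 0.0013). Of 31 proteasome genes 1 rose, 6 fell and 24 were not past the threshold (2 and 7 adjusted over the list alone; adjusted p = 0.4), and the median of -0.23 was 0.03 with quantile normalization and 0.13 with RLE. Fabp1 (adjusted p = 0.27 without the intermediate libraries), Alb (0.2), Apoa2 (0.12), Wdr31 (0.055), Psmb9 (0.25), Psmc2 (0.17), Psmc6 (0.17) and Rps7 (0.25) lost their calls.

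In the adult Uqcr11 rose from 22541 ± 1425 to 36189 ± 2078 CPM (n = 3; 0.68, adjusted p = 0.0015) and Ndufa1 from 10312 ± 1268 to 16496 ± 432 (0.68, 0.02), while Ndufv2 fell from 585 ± 57.1 to 292 ± 8.62 (-0.99, 9.7e-06). Of 75 respiratory chain genes 12 rose, 6 fell and 57 were not past the threshold (14 and 7 adjusted over the list alone; median 0.17, adjusted p = 1.8e-04, and adjusted p = 0.9 with an estimated correlation). Tnni1, the slow troponin I, rose from 171 ± 14.5 to 307 ± 37 (0.84, 1.2e-04) and Tnni2, the fast form, from 21437 ± 1278 to 26974 ± 1303 (0.33, 0.0088), although Tnni2 was at -0.08 with quantile normalization. Myf6, a myogenic factor, fell from 58.6 ± 18.6 to 13.5 ± 1.59 (adjusted p = 1.1e-04). The matrix genes Dcn (144 ± 34.8 against 267 ± 9.96; -0.91, 0.0075) and Mfap5 (26 ± 2.39 against 58.6 ± 16.6; -1.10, 0.001) were lower. Uqcr11 (adjusted p = 0.2 without the intermediate libraries), Ndufa1 (0.52), Ndufv2 (0.068), Tnni1 (0.2), Tnni2 (0.47), Myf6 (0.1), Dcn (0.42) and Mfap5 (0.33) lost their calls. Of 16 fibroblast and connective tissue genes 0 rose, 4 fell and 12 were not past the threshold (0 and 4 adjusted over the list alone; median -0.65, adjusted p = 0.0034, and adjusted p = 0.9 with an estimated correlation). This list also made up a smaller share of Cre-positive libraries at all 4 ages, for instance 0.0507 ± 0.0103% against 0.0802 ± 0.0103% in the adult (exact permutation p = 0.1, the smallest possible).

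Rpl22 was lower in adult Cre-positive diaphragm, at 13.5 ± 1.65 against 23.6 ± 1.81 CPM (n = 3; -0.77, adjusted p = 0.047, and 0.76 without the intermediate libraries). Acta1 (36518 ± 2736 against 34074 ± 3333; 0.10, 0.56) and Ckm (5308 ± 204 against 5415 ± 637; -0.02, 0.99) were not past the threshold. Of 17 motor neuron and cholinergic genes 1 rose, 1 fell and 15 were not past it (1 and 2 adjusted over the list alone; adjusted p = 0.54). In total 1659 genes were past the threshold, 424 higher and 1235 lower, and 14 without the intermediate libraries (1042 at unadjusted p under 0.05). With RLE size factors 969 were higher and 794 lower, with quantile normalization 858 and 910, and the median of all genes moved from -0.12 to 0.03 with RLE. The count was 844 without Cre-negative replicate 1 and 909 without Cre-positive replicate 3.

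Genes higher in Cre-positive diaphragm overlapped between neighbouring ages up to P10. Of the genes higher in Cre-positive diaphragm, 211 were shared by E15.5 and P0.5, among them Mia, Col2a1, Ucma, Comp, Col9a3 and Cnmd, where 81.6 were expected (Fisher exact p = 3.4e-42). P0.5 and P10 shared 23 against 7 expected (Fisher exact p = 8.5e-08), with Apoc3, Hpx, Asl and Rpl30 among them. P10 and adult shared Apoc3 and Sod1, 2 against 1.78 expected (Fisher exact p = 0.53). With the intermediate libraries left out, E15.5 and P0.5 shared 2 genes against 0.0402 expected (Fisher exact p = 6.5e-04). The other overlaps could not be tested then, since 0 genes were called at P10. Calls at 2 ages come from 1 fit with a shared variance per gene, and the Fisher test takes genes as independent. A gene of low variance is more easily called at both ages, so these p-values do not measure a shared difference. Past the threshold and higher at all 4 ages were 0 genes; lower at all 4 were As3mt, Myzap and Ndufc2, none of them past it without the intermediate libraries. Chosen after these overlaps were seen, As3mt, an arsenic methyltransferase, differed by -1.01, -1.27, -1.61 and -1.31 from E15.5 to adult (adjusted p = 0.011, 7.5e-04, 0.0013 and 0.0012). Myzap differed by -1.31, -2.37, -1.52 and -1.23 (adjusted p = 0.023, 9.7e-05, 0.035 and 0.03; at E15.5 -0.84 and 0.11 without Cre-negative replicate 1), and Ndufc2, a complex I subunit, by -0.64, -0.42, -0.56 and -0.42 (adjusted p = 2.0e-04, 0.0028, 0.0028 and 0.0055), although the P0.5 difference of Ndufc2 was 0.01 with RLE.

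The Cre difference itself changed between ages for Apoc2, Col2a1, Mia and Abracl. Between E15.5 and P0.5, Apoc2 in Cre-negative diaphragm went from 1179 ± 256 to 0.291 ± 0.056 CPM but in Cre-positive diaphragm from 1643 ± 340 to 487 ± 552 (n = 3), so its Cre difference rose by 7.46 (adjusted p = 3.3e-06, and 0.013 without the intermediate libraries). From P0.5 to P10 the Apoc2 difference fell again (-7.88, adjusted p = 7.2e-07, and 0.011 without them), as did those of Col2a1 (-8.25, 7.4e-04, and 0.29 without them) and Mia (-7.39, 3.4e-04, and 0.24 without them). Abracl was at 50.3 ± 22.1 in Cre-positive and 28.9 ± 7.37 in Cre-negative diaphragm at P10, and its difference fell by 5.15 on the log2 scale to the adult (adjusted p = 3.0e-06, and 0.049 without them). The Cre difference was past the threshold for a change in 1371 genes between E15.5 and P0.5 (778 up, 593 down), 1430 between P0.5 and P10 (582 up, 848 down) and 583 between P10 and adult (241 up, 342 down). Without the intermediate libraries the counts were 2, 5 and 1. Simulated libraries without any change, of which 1 in 3 was mixed from the other 2, gave 1572, 1142 and 913 false calls, more than the data for the first and last interval, and 3 independent simulated libraries gave 5, 0 and 0. With RLE size factors the splits were 946 up and 428 down, 460 and 1122, and 365 and 319, and with quantile normalization 760 and 808 from P0.5 to P10. RLE moved the median change of all genes to 0.12, -0.21 and 0.04.

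Of 78 list tests of a changed Cre difference 14 were past the threshold, and 0 with an estimated correlation. For cytosolic ribosomal protein genes (79 tested) 6 went up, 0 down and 73 were short of the threshold from E15.5 to P0.5 (6 and 0 adjusted over the list alone; adjusted p = 0.0043, and adjusted p = 0.91 with an estimated correlation). From P10 to adult 0 went up, 11 down and 68 were short of it (0 and 15 adjusted over the list alone; median -0.26, adjusted p = 5.1e-07, and adjusted p = 0.83 with an estimated correlation). Of 75 respiratory chain genes 0 went up, 14 down and 61 were short of it from P0.5 to P10 (0 and 19 adjusted over the list alone; adjusted p = 7.5e-04, and adjusted p = 0.91 with an estimated correlation). Of 15 Schwann cell genes 0 went up, 4 down and 11 were short of it from P0.5 to P10 (0 and 4 adjusted over the list alone; median -1.05, adjusted p = 0.018, and adjusted p = 0.39 with an estimated correlation). Of 7 adipocyte genes 0 went up, 3 down and 4 were short of it from P10 to adult (0 and 4 adjusted over the list alone; median -1.04, adjusted p = 0.0014, and adjusted p = 0.076 with an estimated correlation). Leaving out 1 library moved the 1371 genes to 904 (Cre-negative E15.5 replicate 2) or 857 (Cre-positive E15.5 replicate 3), and the 1430 genes to 808 or 895 (Cre-negative or Cre-positive P10 replicate 3). It moved the 583 genes to 325 or 350 (the same P10 replicates), 327 (adult Cre-negative replicate 1) or 339 (adult Cre-positive replicate 3).

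Cholinergic and axonal transcripts were far lower in Cre-positive diaphragm than in spinal cord. At E15.5 Chat was at 0.0784 ± 0.0787 against 15.9 ± 0.261 CPM (n = 3; log2 difference -3.97, adjusted p = 5.4e-17), Slc18a3 at 0.549 ± 0.661 against 233 ± 25.2 (-7.32, 1.1e-17) and Slc5a7 at 0.302 ± 0.107 against 64.5 ± 2.69 (-5.66, 2.9e-19). Calca, the CGRP precursor, was at 0.0857 ± 0.0763 against 596 ± 141 (-9.08, 2.6e-13) and Prph, a peripheral neuron intermediate filament, at 46.2 ± 9.89 against 1666 ± 95.8 (-5.16, 4.9e-08). Nefm, a neurofilament subunit, was at 7.46 ± 1.77 against 2404 ± 145 at E15.5 (-8.17, 2.7e-19), 1.2 ± 0.105 against 2868 ± 178 at P0.5 (-10.35, 6.5e-21), 0.714 ± 0.295 against 4086 ± 257 at P10 (-11.23, 3.5e-21) and 1.16 ± 0.552 against 4961 ± 123 in the adult (-11.20, 2.4e-21). At P0.5 Slc5a7 was at 0.00338 ± 0.00586 against 36.9 ± 5.17. The presynaptic gene Snap25 was at 0.25 ± 0.163 against 2228 ± 5.82 in the adult (-10.81, 3.7e-22).

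Slc18a3 differed by -7.92 at P0.5 (0.0473 ± 0.0457 against 253 ± 20.6 CPM, n = 3; adjusted p = 2.7e-18), -7.17 at P10 (0.0682 ± 0.072 against 152 ± 9.25; 1.5e-17) and -7.32 in the adult (0.0693 ± 0.00908 against 170 ± 3.22; 9.4e-18). Of 27 motor neuron and cholinergic genes 25, 27, 25 and 24 were lower in diaphragm from E15.5 to adult, and 0, 0, 1 and 1 higher (adjusted p with an estimated correlation 0.0022, 0.0022, 0.0027 and 0.0067). Of 39 axonal cytoskeleton genes 39, 39, 39 and 37 were lower and 0 higher at any age (medians -5.33, -6.11, -5.75 and -6.03; adjusted p with an estimated correlation 5.0e-04, 5.0e-04, 5.0e-04 and 1.0e-03). All 42 synaptic vesicle genes (0.0015, 0.0016, 0.0015 and 0.0022, likewise) and all 25 neurotransmitter receptor genes (0.005, 0.0086, 0.0075 and 0.023) were lower at each age. Of 24 voltage-gated channel genes 24, 22, 22 and 20 were lower and 0, 0, 2 and 2 higher (adjusted p = 4.0e-08, 2.6e-06, 7.3e-06 and 1.7e-04, and adjusted p = 0.051, 0.082, 0.088 and 0.14 with an estimated correlation). Of 8 sensory neuron genes 6, 5, 6 and 4 were lower and 0, 1, 1 and 1 higher (adjusted p = 0.33, 0.69, 0.49 and 0.9). The adult sensory neuron test pointed up against a median of -0.29.

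Muscle transcripts were higher in diaphragm than in spinal cord at every age. Acta1, skeletal actin, was higher in diaphragm by 4.49, 4.26, 8.63 and 13.71 from E15.5 to adult (adjusted p = 3.9e-08, 6.9e-08, 1.3e-12 and 6.7e-16), and Ckm, muscle creatine kinase, by 4.57, 5.58, 8.04 and 12.09 (2.9e-07, 1.4e-08, 5.1e-11 and 6.2e-14). In the adult Mb, myoglobin, was at 13337 ± 22.2 against 0.253 ± 0.133 CPM (n = 3; 13.38, adjusted p = 1.1e-19). Of 38 skeletal muscle contractile genes 35, 37, 36 and 35 were higher and 1, 1, 0 and 1 lower (adjusted p with an estimated correlation 0.085, 0.051, 0.052 and 0.048; medians 4.29, 5.19, 6.22 and 7.18). Chrng, the fetal acetylcholine receptor subunit, was at 43.7 ± 7.05 against 0.59 ± 0.305 at E15.5 (4.82, 5.7e-13), and Chrnd at 16.4 ± 1.55 against 0.302 ± 0.0849 at P0.5 (3.74, 2.1e-07). Ache, which motor neurons also express, was lower in diaphragm (-4.48, -5.92, -4.06 and -3.77; adjusted p = 3.9e-08, 4.7e-10, 1.5e-07 and 3.6e-07). Of 17 neuromuscular junction genes 9, 10, 11 and 9 were higher and 3, 5, 4 and 4 lower (adjusted p = 0.0029, 5.1e-04, 3.5e-04 and 0.005, and adjusted p = 0.048, 0.023, 0.021 and 0.051 with an estimated correlation). Mymx, a myoblast fusion peptide, was at 31.1 ± 3.37 against 0.603 ± 0.548 at P0.5 (4.38, 1.1e-13), and of 9 satellite cell genes 8, 8, 9 and 4 were higher and 0, 1, 0 and 1 lower (adjusted p = 8.1e-07, 2.6e-06, 1.0e-06 and 0.01, and adjusted p = 0.0022, 0.0027, 0.0022 and 0.066 with an estimated correlation).

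Liver transcripts were abundant in E15.5 diaphragm of either genotype and nearly absent from spinal cord at that age. In Cre-positive diaphragm Alb was at 2746 ± 34.8 against 6.2 ± 4.89 CPM (n = 3; 8.95, adjusted p = 2.1e-09), Afp, the fetal albumin relative, at 2217 ± 112 against 4.34 ± 2.93 (8.90, 6.9e-10), Apoc2 at 1643 ± 340 against 1.68 ± 1.01 (9.32, 6.1e-12) and Fabp1 at 1113 ± 207 against 0.93 ± 0.918 (9.27, 8.7e-09). Alb was at 3602 ± 84.1 and Afp at 4664 ± 446 in Cre-negative diaphragm at this age. All 25 cell cycle genes were higher in diaphragm at E15.5 (median 2.65, adjusted p = 1.1e-14, and adjusted p = 0.025 with an estimated correlation), and 3 were higher and 4 lower in the adult (adjusted p = 0.1). Endothelial genes were higher, 8, 10, 11 and 11 of 11 from E15.5 to adult, with 0 lower (adjusted p = 1.3e-04, 1.1e-07, 2.0e-09 and 5.4e-09, and adjusted p = 0.14, 0.064, 0.048 and 0.048 with an estimated correlation). Fibroblast genes were higher for 15, 15, 15 and 13 of 16, with 0 lower (adjusted p with an estimated correlation 0.082, 0.048, 0.051 and 0.082). Of 16 microglia and macrophage genes 13, 5, 9 and 5 were higher and 0, 3, 2 and 3 lower (adjusted p = 6.6e-06, 0.0038, 0.0011 and 0.012, and adjusted p = 0.023, 0.098, 0.073 and 0.14 with an estimated correlation).

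Myelin and lipid synthesis genes favored the spinal cord. Mbp, a myelin sheath protein, was at 51.6 ± 15.4 CPM in diaphragm against 12322 ± 2137 in spinal cord at P10 (n = 3; -7.90, adjusted p = 1.6e-11). Of 16 oligodendrocyte lineage genes 12, 14, 15 and 14 were lower and 1, 0, 0 and 1 higher from E15.5 to adult (adjusted p = 0.16, 0.001, 2.5e-06 and 1.6e-04, and adjusted p = 0.49, 0.12, 0.048 and 0.085 with an estimated correlation). Of 23 cholesterol synthesis genes 18, 22, 23 and 22 were lower and 0 higher at any age (adjusted p = 0.0096, 4.3e-04, 1.9e-05 and 3.5e-04, and adjusted p = 0.32, 0.17, 0.12 and 0.16 with an estimated correlation). Of 46 translation factor genes 24, 28, 29 and 30 were lower and 8, 8, 6 and 8 higher (adjusted p = 0.98, 0.66, 0.24 and 0.36), but with quantile normalization the medians were above 0 at each age (0.33, 0.22, 0.09 and 0.22). The E15.5 and P0.5 tests of this list pointed up against medians of -0.31 and -0.64. Rpl22 differed by -0.32, -1.65, -0.53 and -1.42 (adjusted p = 0.029, 4.2e-10, 0.0011 and 4.0e-09), and with quantile normalization by 0.51 at E15.5 and 0.46 at P10.

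Of 14831 tested genes 10922, 11164, 10833 and 11090 were past the threshold between Cre-positive diaphragm and spinal cord from E15.5 to adult. The higher and lower genes numbered 3189 and 7733, 2722 and 8442, 2952 and 7881, and 2895 and 8195. The scaling sets this split, since the median of all genes was -0.58, -0.80, -0.63 and -0.72, and 0.01, 0.09, 0.06 and 0.02 with quantile normalization. Quantile normalization gave 5101 higher and 5182 lower, 5590 and 5095, 5305 and 4979, and 5300 and 5356, and RLE 4570 and 5425, 4416 and 6072, 4258 and 5907, and 4469 and 6186. Adjusted over each list alone, the list counts given for these tissue comparisons moved by at most 1 gene. Without the intermediate libraries 8265, 8855, 8306 and 8965 genes were past the threshold.

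In the spinal cord libraries, glial genes rose from E15.5 to P0.5. Without a Cre-negative spinal cord sample, a change of the background and one in ChAT-Cre cells cannot be told apart, here or at the later ages. Mbp rose from 39.7 ± 8.42 to 627 ± 24 CPM (n = 3; log2 difference 3.97, adjusted p = 3.1e-07) and Mobp from 1.61 ± 0.337 to 34.8 ± 1.57 (3.78, 1.7e-08). Of 16 oligodendrocyte lineage genes 15 rose, 0 fell and 1 was not past the threshold (15 and 0 adjusted over the list alone; median 1.35, adjusted p = 3.5e-08, and adjusted p = 0.79 with an estimated correlation). Gfap, the astrocyte filament, rose from 14.7 ± 6.77 to 103 ± 3.04 (2.82, 1.9e-05) and Agt from 5.1 ± 1.67 to 51.3 ± 6.12 (3.13, 3.8e-08). Of 13 astrocyte genes 11 rose, 0 fell and 2 were not past it (11 and 0 adjusted over the list alone; median 0.90, adjusted p = 1.9e-04, and adjusted p = 0.79 with an estimated correlation). The metallothionein Mt2 rose from 20.6 ± 3.28 to 577 ± 99.8 (4.74, 6.1e-12) and Mt1 from 95.4 ± 17.1 to 1667 ± 338 (4.11, 5.6e-10). Hoxc10 rose from 0.828 ± 0.0991 to 39 ± 0.956 (4.45, 1.1e-14) and Hoxd9 from 0.574 ± 0.169 to 21 ± 0.654 (3.81, 3.2e-12).

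**Figure D4:**
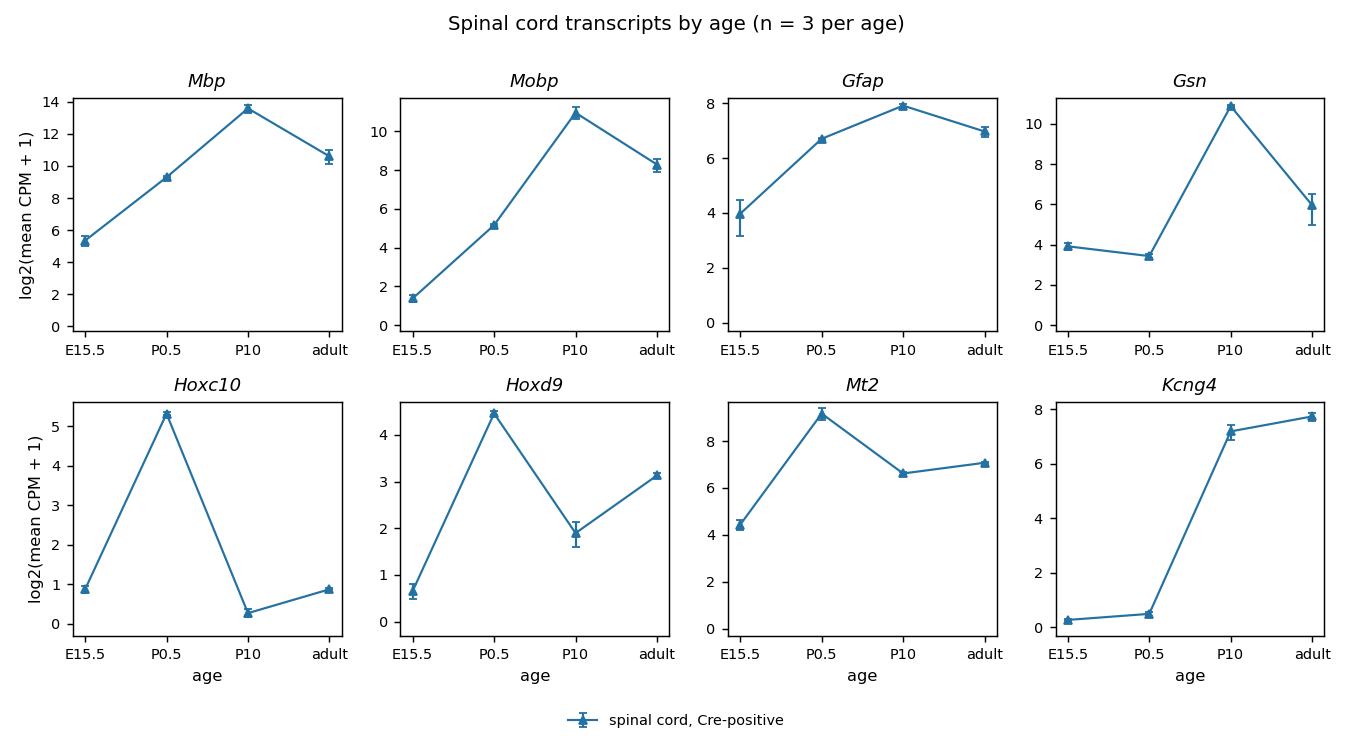
Glial (Mbp, Mobp, Gfap), actin-severing (Gsn), Hox (Hoxc10, Hoxd9), metallothionein (Mt2) and potassium channel (Kcng4) transcripts in Cre-positive spinal cord over age. Points are mean and SD of 3 libraries in CPM on a log2 scale after adding 1.

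Ibsp, Bglap and Spp1, genes of bone matrix, fell over the same interval. Ibsp fell from 74 ± 21.9 to 3.85 ± 0.402 CPM (n = 3; -3.91, adjusted p = 2.5e-10), Bglap from 27.4 ± 7.26 to 2.38 ± 1.24 (-3.10, 1.7e-06) and Spp1 from 278 ± 9.14 to 36.7 ± 3.11 (-2.89, 1.8e-12). Isl1, a motor neuron transcription factor, fell from 140 ± 19.4 to 44.8 ± 2.32 (-1.61, 3.2e-10), Chat from 15.9 ± 0.261 to 11.5 ± 1.2 (-0.44, 4.0e-04) and Slc5a7 from 64.5 ± 2.69 to 36.9 ± 5.17 (-0.80, 6.2e-07), while Slc18a3 was at 253 ± 20.6 against 233 ± 25.2 (0.12, 0.17). Of 27 motor neuron and cholinergic genes 6 rose, 15 fell and 6 were not past the threshold (6 and 15 adjusted over the list alone; median -0.44, adjusted p = 0.43). Rpl22 was at 51.1 ± 2.7 against 58.5 ± 6.05 (-0.19, 0.029), Acta1 at 1535 ± 975 against 384 ± 119 (1.78, 0.047) and Ckm at 160 ± 110 against 88.8 ± 34.3 (0.60, 0.53; P0.5 106 without replicate 1). Of 13 spinal interneuron genes 9 rose, 1 fell and 3 were not past the threshold (9 and 1 adjusted over the list alone; median 0.60, adjusted p = 0.02, and adjusted p = 0.79 with an estimated correlation). Of 21 cell cycle genes 1 rose, 17 fell and 3 were not past it (1 and 17 adjusted over the list alone; median -0.64, adjusted p = 0.022, and adjusted p = 0.79 with an estimated correlation). In total 9668 of 13373 tested genes were past the threshold from E15.5 to P0.5, 3732 higher and 5936 lower, and 7357 without the intermediate libraries. With RLE size factors 4835 were higher and 4716 lower, and the median of all genes moved from -0.13 to 0.01.

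From P0.5 to P10 myelin genes rose further. Mog rose from 3.59 ± 0.263 to 158 ± 3.99 CPM (n = 3; 5.12, adjusted p = 6.9e-13), Mobp from 34.8 ± 1.57 to 1979 ± 415 (5.77, 2.3e-10) and Mbp from 627 ± 24 to 12322 ± 2137 (4.28, 9.5e-08). Of 16 oligodendrocyte lineage genes 15 rose, 0 fell and 1 was not past the threshold (15 and 0 adjusted over the list alone; median 2.39, adjusted p = 4.5e-07, and adjusted p = 0.79 with an estimated correlation). Gsn, an actin-severing protein that oligodendrocytes also make, rose from 9.78 ± 0.825 to 1892 ± 52 (7.46, 1.5e-08) and Myo6 from 1.88 ± 0.224 to 137 ± 7.24 (5.58, 2.5e-07).

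Kcng4, Kcna1, Glra1 and Chat rose between P0.5 and P10. Kcng4, a potassium channel modifier, rose from 0.41 ± 0.0727 to 144 ± 27.1 CPM (n = 3; 6.67, adjusted p = 1.8e-15) and Kcna1 reached 119 ± 18 (2.86, 8.6e-13). The glycine receptor subunit Glra1 rose from 17.2 ± 1.87 to 86.7 ± 4.1 (2.28, 3.1e-12) as Glra2, the embryonic form, fell from 53.6 ± 2.8 to 17.4 ± 2.88 (-1.58, 1.2e-09). Chat rose from 11.5 ± 1.2 to 64.9 ± 8.5 (2.40, 2.4e-12) and Slc5a7 from 36.9 ± 5.17 to 64.6 ± 4.01 (0.80, 3.6e-07), whereas Slc18a3 fell from 253 ± 20.6 to 152 ± 9.25 (-0.73, 3.8e-07). Of 27 motor neuron and cholinergic genes 10 rose, 13 fell and 4 were not past the threshold (10 and 13 adjusted over the list alone; median -0.04, 0.01 with quantile normalization and 0.06 with RLE; adjusted p = 0.91). Crabp2, a retinoic acid binder, fell from 85.3 ± 7.74 to 1.95 ± 1.42 (-4.97, 3.3e-08), Ngfr from 71.8 ± 0.78 to 1.79 ± 1.03 (-4.78, 9.6e-09) and Hoxc10 from 39 ± 0.956 to 0.205 ± 0.0867 (-5.05, 9.4e-16). Of 27 axon guidance genes 3 rose, 22 fell and 2 were not past it (3 and 22 adjusted over the list alone; median -0.84, adjusted p = 0.0013, and adjusted p = 0.79 with an estimated correlation). Acta1 fell from 1535 ± 975 to 73.1 ± 49.3 (-4.41, 3.8e-04), Ckm from 160 ± 110 to 12.2 ± 10.7 (-3.73, 0.0028; 106 without P0.5 replicate 1 and 6.64 without P10 replicate 2) and Rpl22 from 51.1 ± 2.7 to 40 ± 1.31 (-0.35, 4.1e-04). In total 10526 genes were past the threshold, 4706 higher and 5820 lower, and 8666 without the intermediate libraries.

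From P10 to adult, the levels of myelin genes in these libraries came down. Mbp fell from 12322 ± 2137 to 1551 ± 456 CPM (n = 3; -3.02, adjusted p = 2.6e-06) and Mobp from 1979 ± 415 to 310 ± 69.5 (-2.67, 3.2e-07). Of 16 oligodendrocyte lineage genes 0 rose, 15 fell and 1 was not past the threshold (0 and 15 adjusted over the list alone; median -1.42, adjusted p = 2.9e-04, and adjusted p = 0.81 with an estimated correlation). Gsn fell from 1892 ± 52 to 61.2 ± 30.3 (-5.05, 5.7e-07), Lima1 from 59.5 ± 7.64 to 1.03 ± 0.577 (-4.94, 1.4e-10) and Myo6 from 137 ± 7.24 to 5.88 ± 3.71 (-4.48, 2.5e-06). Glra2 fell further, from 17.4 ± 2.88 to 0.998 ± 0.176 (-3.19, 3.5e-12). Of 25 neurotransmitter receptor genes 1 rose, 20 fell and 4 were not past it (1 and 20 adjusted over the list alone; median -0.48, adjusted p = 0.016, and adjusted p = 0.91 with an estimated correlation).

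Psmc5 and Junb were higher in adult spinal cord than at P10. Psmc5 rose from 516 ± 3.95 to 1131 ± 19.2 CPM (n = 3; 1.13, adjusted p = 6.1e-11), and of 31 proteasome genes 20 rose, 5 fell and 6 were not past the threshold (21 and 5 adjusted over the list alone; median 0.20, adjusted p = 2.9e-04, and adjusted p = 0.79 with an estimated correlation). Junb rose from 4.28 ± 0.576 to 11 ± 0.64 (1.19, 3.8e-08), and of 12 immediate early genes 8 rose, 0 fell and 4 were not past it (8 and 0 adjusted over the list alone; median 0.38, adjusted p = 0.0052, and adjusted p = 0.57 with an estimated correlation). Klk6, an oligodendrocyte protease, rose from 4.81 ± 0.0885 to 47.6 ± 0.436 (3.06, 1.0e-13), Cd24a from 55.3 ± 11.9 to 300 ± 15.3 (2.44, 1.4e-09) and Tspo from 11.5 ± 1.92 to 59.5 ± 1.04 (2.29, 3.2e-11). The liver gene Fabp1, listed at 0 at P10, was at 94.6 ± 85.4 in the adult (adjusted p = 0.0018, and 0.078 without the intermediate libraries), and at 53.8 without adult replicate 2. Chat was at 64.6 ± 3.09 against 64.9 ± 8.5 (0.00, 1), Slc18a3 at 170 ± 3.22 against 152 ± 9.25 (0.16, 0.085) and Rpl22 at 37.5 ± 0.82 against 40 ± 1.31 (-0.09, 0.28), while Slc5a7 rose to 80.7 ± 2.14 (0.32, 0.0036). Acta1 fell from 73.1 ± 49.3 to 1.76 ± 0.572 (-4.47, 5.0e-04) and Ckm from 12.2 ± 10.7 (6.64 without replicate 2) to 0.218 ± 0.0665 (-3.00, 0.011). In total 9079 genes were past the threshold, 3153 higher and 5926 lower, and 6338 without the intermediate libraries. Quantile normalization gave 4881 higher and 4017 lower and moved the median of all genes from -0.16 to 0.05, and RLE gave 4882 and 4337.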

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

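Most tests in this part were written before their result was seen; those on the complexity of the Cre-negative libraries and on transcripts of ChAT-Cre cells were written after it, as were the fits without the intermediate libraries or without an outer library.

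A change of the Cre difference in diaphragm was called for 1371 genes from E15.5 to P0.5, 1430 from P0.5 to P10 and 583 from P10 to adult. Simulated libraries without any change, 1 in 3 mixed from the other 2, gave 1572, 1142 and 913 calls, so the first and last count do not exceed what such a structure gives. Apoc2 changed by 7.46 from E15.5 to P0.5, Apoa1 by 6.18, Ttr by 5.93 and Mlkl by -5.27. From P0.5 to P10 Apoc2 changed by -7.88, Col2a1 by -8.25 and Mia by -7.39. From P10 to adult Abracl changed by -5.15 and Fam92a by -4.56. Of these, Apoc2 in both intervals and Abracl kept their calls without the intermediate libraries, when 2, 5 and 1 genes were called in all.

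The first pattern is the library of each group that lies between the other 2. A mixture of the outer libraries would leave few genes seen only in the intermediate library, and the ratio of such genes to those of an outer library was 0.423 (26 genes against 61.5, with a 95% range of 0.276 to 0.619), which leaves a mixture and an independent library that cannot be told apart by this count. A shared technical axis is argued against by the outer differences of different groups, whose median absolute correlation was 0.0304 over 34 pairs (largest 0.194). Genes with many reads in 1 outer library and 0 in the other stood in the intermediate library at close to its fitted weight. In Cre-negative diaphragm at P0.5 the median ratios were 0.211 and 0.793 against weights of 0.207 and 0.789. The weights were fitted to reads that include these genes, and the library was chosen for its fit, so part of this closeness was set in advance. The comparison was also not among the tests written beforehand. With these limits it argues against 3 independent libraries in diaphragm. Whether the libraries are technical repeats or pools stays open, as does the structure in spinal cord.

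The second pattern is the liver and cartilage transcript of Cre-positive diaphragm at P0.5, which may come from neighbouring tissue. Liver genes not looked at before differed by a median of 1.71 at P0.5, with 30 of 30 tested members above 0 out of 34 listed, but by -0.50 at E15.5 (9 of 30 above 0), 0.71 at P10 (24 of 30) and 0.43 in the adult (25 of 30), so liver carried over in excess with Cre-positive tissue matches P0.5, less so P10 and adult age, and at E15.5, with liver transcript in both genotypes (2.13% and 2.42%), no such excess was seen. Much of the P0.5 liver transcript came from Cre-positive replicate 2, with Apoc2 at 1120 CPM there and at a mean of 169 without it. Apoc2 still differed by 7.02 and Fabp1 by 5.06 without that library, but the libraries left were close to each other. The other liver genes were not tested without it. Other cartilage genes differed by a median of 0.61 with 11 of 16 above 0 (1.09 at E15.5, -0.09 at P10 and -0.08 in the adult), so rib or sternal cartilage and no cartilage cannot be told apart. For transcripts of ChAT-Cre cells of the kind in spinal cord, 11 motor neuron and cholinergic transcripts abundant in cord were examined. They reached a median of 0.251% of their cord level in Cre-positive diaphragm at P0.5 (quartiles 0.113% and 0.812%), which argues against such cells. Liver and cartilage made up 0.961 ± 1.11% and 0.0559 ± 0.0225% there against 0.0321% and 0.0196% in cord. Both lists include genes listed because they were seen higher in Cre-positive diaphragm, so this part of the test was partly set in advance and adds no support. A lower complexity of the Cre-negative libraries and its absence cannot be told apart, since 15 of the 20 members at 50 CPM or more (median 5.45) were listed because they were seen higher, and an effect of genotype stays open as untested.

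The last pattern is the P0.5 peak of Hox genes of paralog groups 9 and 10 in spinal cord, which could reflect a more caudal stretch of cord. Other genes of groups 9 to 11 exceeded both neighbouring ages by a median of 0.52, but only 4 were tested and 2 of them were above 0.5, so a caudal level and its absence cannot be told apart; groups 4 to 6 had a median of -0.73 over 10 genes. No single library decides the level, as the median rise of groups 9 to 11 from E15.5 was at least 2.75 without any P0.5 library (2.79 with all, over 8 genes). These genes include those in which the peak was first seen. Whether the P0.5 libraries are independent samples is open, so a single sample behind all of them is not excluded. A change of these genes with age itself stays open as untested.

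Exchanging labels between libraries allows only 10 splits in each comparison of 3 against 3, too few for a share under 0.05, and in each of these comparisons 1 split, the real one, gave as many genes as the real labels. The highest other split gave 100 genes against 1522 at E15.5, 953 against 3844 at P0.5, 4 against 201 at P10 and 20 against 1659 in the adult for the Cre comparisons. For Cre-positive diaphragm against spinal cord it gave 5 against 10922, 1 against 11164, 0 against 10833 and 0 against 11090, and between ages of spinal cord 0 against 9668, 0 against 10526 and 0 against 9079. For the changes of the Cre difference, 3, 4 and 2 of 100 splits gave as many genes as the real labels. The highest other splits gave 3851, 2528 and 1211 genes, each with Cre labels exchanged at the earlier age, a split that adds the Cre differences of both ages in place of subtracting them, so a difference shared by both ages raises it.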

How the results depend on the processing

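Most settings were chosen before the data were examined; the edgeR test and the fits without the intermediate libraries or without an outer library of each group were chosen after the data were seen.

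Of the settings tried, leaving out the intermediate library of each group lowered the gene counts of the Cre comparisons most, and the estimated correlation lowered the list calls most. Without these libraries the Cre comparisons gave 7, 108, 0 and 14 genes from E15.5 to adult in place of 1522, 3844, 201 and 1659, and the changes of the Cre difference 2, 5 and 1 in place of 1371, 1430 and 583. The overlap of genes higher at P0.5 and P10 was then 0 because 0 genes were called at P10, while E15.5 and P0.5 shared 2 genes against 0.0402 expected (Fisher exact p = 6.5e-04, with the limit given for these overlaps). Standard errors were then 1.49, 1.52, 1.76 and 1.63 times as large (medians over the named calls from E15.5 to adult; 2 in place of 3 libraries alone give 1.22), and log2 differences nearly the same (1.02, 0.99, 1.01 and 1 times). Without an outer library of each group in their place, the Cre comparisons gave 4844, 6881, 2121 and 4937 genes (lower-numbered outer library left out) or 762, 3131, 16 and 758 (higher-numbered). The changes of the Cre difference gave 4567, 5229 and 3772 or 893, 662 and 123. The intermediate library was chosen as close to a weighted sum of the other 2, so leaving it out leaves the wider pair. The nearly unchanged log2 differences follow largely from that choice. The contrasts in gene counts and standard errors could follow from it or from a mixed library, which these fits do not tell apart. List calls numbered 13, 11, 82 and 23 without the intermediate libraries, in place of 13 for the Cre comparisons, 14 for the changes between ages, 84 for diaphragm against spinal cord and 23 for spinal cord ages. With the estimated correlation 1 of 13 list calls of the Cre comparisons was left, 0 of 14 for the changes between ages, 33 of 84 for diaphragm against spinal cord and 0 of 23 for spinal cord ages.

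Without an expression filter 2434 genes were past the threshold at E15.5 and 365 at P10. edgeR gave 665 at E15.5 (457 higher and 208 lower) and 48 at P10 (34 and 14), and 2179 for the change from P0.5 to P10. DESeq2 gave 599 at P10 and 3010 in the adult, and 2796, 3147 and 1756 for the changes between ages. Fits of only the compared groups gave 1252 at P0.5 and 1196 at P10, and 527 and 1335 for the changes from E15.5 to P0.5 and from P10 to adult. In these fits the gene filter and the variance came from the compared groups alone. The gap between 3844 genes at P0.5 and 201 at P10 thus rests on the choice of fit. Quantile normalization gave 895 for the change from P10 to adult. The cause of the other shifts was not tested.

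Leaving out 1 library gave 693 to 1538 genes at E15.5, 2713 to 4185 at P0.5, 44 to 155 at P10 and 844 to 1639 in the adult. The ranges were 857 to 1926, 808 to 1983 and 325 to 820 for the changes between ages. For diaphragm against spinal cord they were 10272 to 10594, 10570 to 11362, 10196 to 10552 and 10538 to 11006, and for spinal cord ages 8947 to 9390, 9934 to 10217 and 8248 to 8742.

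Replicate number as a block gave 1457, 3773, 165 and 1572 genes for the Cre comparisons, with no comparison in which every sample correlated best with its own number. The deviations of same-numbered libraries correlated at -0.11 to 0.10. Library totals without a TMM factor equal the CPM scaling, and a filter at 1 count equals no filter, so neither was run separately. The other settings for tissue and spinal cord age stayed within 1.5 times the count given.

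Of 88 named calls in the Cre comparisons 16 were kept in every setting, of 9 changes between ages 3, of 46 tissue calls 43 and of 49 spinal cord age calls 44. Leaving out 1 library lost a named call 86 times in the Cre comparisons, 4 times between tissues and 9 times between spinal cord ages. Few named genes turned their direction. Ckm at P0.5 was at 0.00 with edgeR, Ndufc2 at P0.5 at 0.01 with RLE, 0.02 with DESeq2 and 0.02 with edgeR, and Tnni2 in the adult at -0.08 with quantile normalization. Rpl22 in diaphragm against spinal cord was at 0.51 (quantile), 0.27 (RLE), 0.28 (DESeq2) and 0.32 (edgeR) at E15.5, and at 0.46, 0.06, 0.06 and 0.23 at P10.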

Other observations

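Some genes of the spinal cord samples were highest at a single age. At P10 Myh10 averaged 327 CPM against 14, 11 and 27.4 at E15.5, P0.5 and adult age, Limch1 325 against 21.7, 12.8 and 18.4, and Arpc1b 467 against 54.4, 38.7 and 34.9. At P0.5 Hoxa10 was at 16.1 CPM against 0.547, 0.367 and 0.3 at the other ages, and Hoxd10 at 19.7 and Hoxa11 at 3.35 against 0 at every other age. Hoxb9 had another course, with 70.9, 33.7, 20.1 and 10.8 CPM from E15.5 to adult. These genes were picked after the data were seen.

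The acetylcholine receptor subunits Chrng and Chrne had their highest mean levels at different ages in Cre-negative diaphragm. Chrng, the fetal subunit, averaged 25.9, 6.84, 2.03 and 0 CPM from E15.5 to adult, and Chrne, the adult subunit, 0, 0, 14.5 and 3.96. In Cre-positive diaphragm Chrng averaged 43.7, 9.41, 1.64 and 0 and Chrne 0.442, 0.702, 6.06 and 4.33. Changes with age within diaphragm were not tested here.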
